A study of Homo sapiens with 6 samples.

How the data were processed

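RNA was measured by sequencing in 6 libraries from MCF7, a human breast cancer cell line, per the labels. All 6 carried a stable short hairpin RNA against SRPK2, a kinase of serine/arginine-rich splicing proteins. The labels put 3 libraries in the group re-expressing wild-type SRPK2 (WT) and 3 in the group re-expressing the 4A mutant, which the series' design text calls deficient in O-GlcNAcylation, the attachment of a single sugar to proteins. The libraries were made from 1 µg of total RNA with the NEBNext Ultra RNA kit, per the labels' protocols. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

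The submitters' processing notes name STAR 2.7.0, HTSeq 0.11.2 and the genome build GRCh38. The annotation and the normalization step were not given in the sources used here. The deposited signal was a normalised value per gene and library that was not a whole number. In each library every positive value was a whole multiple of its own step, and dividing by that step gave whole numbers within 0.001 reads for 100% of positive values. The deposited values were therefore treated as gene read counts divided by 1 factor per library. The factors recovered this way, 0.967 to 1.07, matched the median-of-ratios factors computed here from these 6 libraries. The recovered totals were 23320937 to 25732978 reads per library, and that depth sets the counting error of each value. Intervals on shares of reads are exact Clopper-Pearson 95% intervals, and a gene with no reads is given a floor of 3 counts. Intervals and floors cover counting error only, since no molecular identifiers are described.

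The files hold 58735 Ensembl gene identifiers. All 58735 matched GENCODE release 29 (GRCh38) without version, and 58207 were in the gene symbol table. Positions, gene types, transcript lengths and GC content came from that release. Of identifiers that share a symbol, the one with the highest mean was used for gene lists.

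The count test that had been planned, edgeR's quasi-likelihood test on raw counts, was not kept as the main test because the deposited values were not raw counts. It could be run on the recovered reads and is given as an alternative. The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a variance trend and robust empirical Bayes moderation. It was run on the 16643 genes with a value of at least 10 in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. These limma settings were set once the unit was known; they were the first tried and were not altered. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. On the recovered reads edgeR 4.0.16 called 361 genes, 350 of them also called by limma.

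The gene lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The 24 lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives. With an estimated correlation camera has only the residual degrees of freedom of the libraries, which are few here, so that setting has little power. camera was given a variance trend to match the gene test, a setting chosen after first values without it had been seen. Fry tests whether the genes of a list move one way on balance, and does not compare the list with other genes. Named genes were SRPK2, then ACLY, ACSS2, ACACA, FASN, SCD and SREBF1 whatever their values. To these were added the 10 protein-coding genes with the largest change in each direction among those past the threshold, with a mean CPM of at least 5 and no overlap of CPM between groups. Of each list, up to 4 members with the smallest adjusted p were added. Genes named outside this rule, which are cell markers, genes that set one library apart, HSPA5, OGT, OGA and ISG20, were chosen after their values were seen.

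Because the library labelled WT replicate 3 differed from its group in SRPK2 and in many other genes, values without it are printed beside many results, a choice made after seeing the data. Leaving out each library in turn had been fixed beforehand. The first set of alternatives held library size scaling, no filter, a stricter filter (CPM of at least 1 in at least 3 libraries), a replicate block, DESeq2 1.42.0, limma-voom, removal of GC and length trends (splines with 5 degrees of freedom) alone and with the replicate block, and leaving out each library. DESeq2's size factors in the planned edgeR fit gave no separate alternative, since the deposited values already carry such factors. Removal of GC and length trends had been fixed for the count of genes and was added later for the other results. Further alternatives added later were edgeR on recovered reads, TMM factors, pseudocounts of 0.5 and 4, library weights, moderation without the robust option, and camera without the variance trend. So were edgeR, fry, the estimated correlation and camera without the trend over the 5 libraries without WT replicate 3.

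Methods were tested on simulated reads of 16643 genes with 200 genes changed. With the spread of the 6 libraries, limma recovered 1.49% of genes changed by 0.5 on the log2 scale, 37.3% of those changed by 1 and 83.3% of those changed by 2, and 10 of its 91 calls were unchanged genes. With the spread of the 5 libraries without WT replicate 3, it recovered 44.8%, 73.1% and 93.9%, and 8 of its 149 calls were unchanged genes. Both shares of unchanged genes were above 0.05, the one for the 5 libraries only slightly, and each comes from 1 draw. At such a threshold some of the genes called here are expected to be false. The 200 changed genes are far fewer than the 3865 called in the data without WT replicate 3. The shares recovered and falsely called depend on that number, so they may not hold for the data. The simulation drew genes independently, with the same dispersion in every library. In the data WT replicate 3 sets most of the spread, so the shares simulated for the 6 libraries may not hold for them. Libraries of a group were compared by a chi-square of their reads over genes, and every pair differed by more than sampling noise: the lowest mean per gene was 4.50, between WT replicates 1 and 2. Whether strand was used in counting was not given in the sources used here, so reads of overlapping genes cannot be told apart.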

Results

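Gene expression was compared in 6 RNA sequencing libraries labelled MCF7, all with an SRPK2 hairpin. The labels put 3 in the group re-expressing wild-type SRPK2 (WT) and 3 in the group re-expressing the O-GlcNAcylation-deficient 4A mutant. Recovered depth was 23604458, 23320937 and 25566538 reads in WT replicates 1 to 3 and 23324670, 25732978 and 23805042 reads in 4A replicates 1 to 3. Values are normalised read counts, as mean ± SD with n = 3 per group unless a library is named.

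SRPK2 (ENSG00000135250, GRCh38 chromosome 7, 105110704 to 105399308), the targeted and re-expressed gene, was at 1139287 and 1162054 in WT replicates 1 and 2 and at 1412177, 1290432 and 1186768 in 4A replicates 1 to 3. In the library labelled WT replicate 3 it was at 80588, 14.3-fold below the mean of the other WT libraries. SRPK2 took 0.338% of reads there (exact 95% interval 0.336 to 0.340%), against 4.77% and 4.87% in WT replicates 1 and 2 and 5.35% ± 0.503 in 4A. That library differed from its group in the re-expressed gene, and directions drawn from the WT group rest partly on it. Over all 6 libraries the difference in SRPK2 between the groups did not pass the threshold (log2 fold change 1.45, SE 0.93, limma adjusted p = 0.389). Without the library labelled WT replicate 3 the log2 fold change was 0.17 with SE 0.061 and limma adjusted p = 0.0498, against 0.0838 by edgeR. Gene-level counts cannot separate endogenous from re-expressed transcripts.

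**Figure D1:**
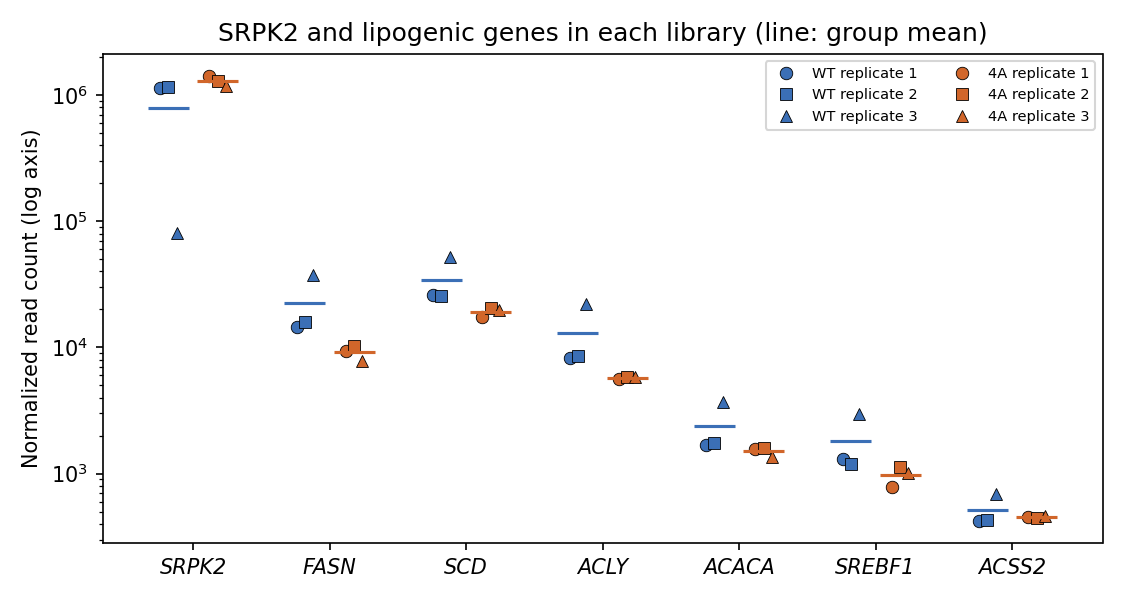
Normalised read counts (log axis) of SRPK2 and 6 lipogenic genes in each library, with blue marks for WT, orange marks for 4A and a line at each group mean. SRPK2 is at 80588 in the library labelled WT replicate 3 and at 1139287 to 1412177 in the other libraries, and that library is also the highest for all 6 lipogenic genes.

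The comparison of 4A with WT asks which transcripts differ when SRPK2 cannot be O-GlcNAcylated. CXCL8, a chemokine that attracts neutrophils (ENSG00000169429, chromosome 4, 73740506 to 73743716), rose from 185 ± 64.6 in WT to 871 ± 93.3 in 4A (log2 fold change 2.29, SE 0.27, limma adjusted p = 0.0239). DDIT4, a stress-induced inhibitor of mTORC1 signalling (ENSG00000168209, chromosome 10, 72273920 to 72276036), rose from 675 ± 98.5 to 1709 ± 99.7 (log2 fold change 1.35, SE 0.13, limma adjusted p = 0.0192). ARPIN, an inhibitor of the actin-nucleating Arp2/3 complex, rose from 424 ± 97.2 to 1160.4 ± 35.8, and the actin-capping genes TMOD1 and TMOD2 rose by 1.46 and 1.26 on the log2 scale. COQ3, a methyltransferase of ubiquinone synthesis, rose from 152 ± 23.5 to 441 ± 58.7. EEF1AKMT2, EYA2, NPL and SRD5A3 completed the 10 largest increases, with log2 fold changes of 1.58, 1.56, 1.43 and 1.28.

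GALR2, a galanin receptor (ENSG00000182687, chromosome 17, 76074794 to 76077541), fell by 2.08 on the log2 scale (SE 0.22, limma adjusted p = 0.0235), from 210 ± 38.4 in WT to 48.6 ± 6.33 in 4A. C11orf54 (ENSG00000182919, chromosome 11, 93741591 to 93764749) fell from 1203 ± 72.5 to 316 ± 37.4 (log2 fold change −1.93, SE 0.13, limma adjusted p = 0.00936). PNPLA6, a lysophospholipase also called neuropathy target esterase, fell from 3141 ± 335 to 1078 ± 156. The lysosomal genes GBA1, encoding glucocerebrosidase, and LAMP1, encoding a membrane glycoprotein, fell by 1.72 and 1.25 on the log2 scale. LGALS3BP, NME2, KCNC3, SRXN1 and TAF10 completed the 10 largest decreases, with log2 fold changes of −1.52, −1.47, −1.35, −1.30 and −1.26. Several of these genes share exonic bases with other annotated genes, so their reads are uncertain: 85.0% of SRXN1, 51.2% of TAF10, 45.0% of TMOD1, 41.2% of DDIT4, 22.9% of NME2, 15.1% of C11orf54 and 14.9% of EEF1AKMT2. GBA1 has a near-identical pseudogene and is uncertain for that reason.

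In all, 360 of 16643 genes passed the limma threshold, 203 higher and 157 lower in 4A, and 91 of them changed by at least 1 on the log2 scale (52 higher, 39 lower). For these 360 genes all 3 4A libraries lay on one side of all 3 WT libraries, as they did for 34.0% of all tested genes, against 10% by chance. At an unadjusted p under 0.05 there were 3658 genes, and edgeR called 361, of which 350 were also called by limma. Without the library labelled WT replicate 3, 3865 genes passed (2086 higher, 1779 lower), 262 of them changed by at least 1 on the log2 scale (157 higher, 105 lower), and the 360 genes were all among them in the same direction. Leaving out any of the other 5 libraries in turn left 0 genes past the threshold by limma or by edgeR, with 2254 to 3827 at an unadjusted limma p under 0.05.

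Genes of cholesterol synthesis and uptake were lower in 4A by camera with the preset correlation (adjusted p = 3.45e-11), but not with an estimated correlation (adjusted p = 0.603 with an estimated correlation) or by fry (0.201). Of 24 measured members, 3 fell over all genes tested, and 20 fell when adjusted over the list alone. MVK, the mevalonate kinase, fell from 1292 ± 68.1 to 753 ± 24.8 (log2 fold change −0.78, SE 0.10, limma adjusted p = 0.0239). The sterol-synthesis enzymes HSD17B7 and NSDHL fell by 0.80 and 0.87 on the log2 scale. SREBF2, the transcription factor that drives this pathway, was at 6878 ± 1491 in WT and 4113 ± 155 in 4A and missed the threshold (log2 fold change −0.72, limma adjusted p = 0.0510). The median log2 fold change of the list was −0.81. In the library labelled WT replicate 3 the members lay a median of 0.82 above the other WT libraries on the log2 scale. Without it the list's median log2 fold change was −0.54 and 20 of 24 members fell over all genes tested, with an adjusted p = 0.224 with an estimated correlation and a fry adjusted p of 0.0125.

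Of the de novo lipogenesis genes, 19 of 24 measured members had a negative log2 fold change and 5 a positive one, but few passed. Of 24 measured members, 1 fell, SLC25A1, the mitochondrial citrate carrier, from 6309 ± 605 to 3890 ± 147 (log2 fold change −0.69, SE 0.093, limma adjusted p = 0.0258), and 3 fell when adjusted over the list alone. The lipogenic genes fixed in advance did not pass the threshold over all 6 libraries. FASN, fatty acid synthase, was at 22663 ± 13116 in WT and 9159 ± 1248 in 4A (log2 fold change −1.17, SE 0.34, limma adjusted p = 0.107). ACLY, ATP citrate lyase, was at 12991 ± 8008 and 5755 ± 107 (log2 fold change −1.01, limma adjusted p = 0.153), and SCD, stearoyl-CoA desaturase, at 34407 ± 15128 and 19250 ± 1516 (log2 fold change −0.76, limma adjusted p = 0.151). Log2 fold changes were −0.80 for SREBF1, −0.56 for ACACA and −0.14 for ACSS2, with limma adjusted p of 0.214, 0.284 and 0.703. Without the library labelled WT replicate 3, where all of these genes were highest, ACLY fell by 0.54 (limma adjusted p = 2.86e-07), FASN by 0.73 (0.000400), SCD by 0.42 (1.96e-05) and SREBF1 by 0.39 (0.0287). ACACA was then at −0.20 (limma adjusted p = 0.0857) and ACSS2 at 0.085 (0.624). The list was lower in 4A by camera with the preset correlation (adjusted p = 0.00234), but not with an estimated correlation (adjusted p = 0.603) or by fry (0.428). Without that library, 8 members fell and 3 rose, and camera's adjusted p was 0.0244 with its variance trend, 0.192 without it and 0.549 with an estimated correlation.

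Hypoxia-response genes were higher in 4A by camera with the preset correlation (adjusted p = 1.69e-08) and by fry (0.00869), but not by camera with an estimated correlation (adjusted p = 0.158 with an estimated correlation). Of 19 measured members, 6 rose over all genes tested and 13 when adjusted over the list alone. NDRG1, a stress- and hypoxia-induced gene, rose from 3255 ± 304 to 6846 ± 90.4 (log2 fold change 1.08, SE 0.089, limma adjusted p = 0.0152). BNIP3, a mitophagy receptor, rose from 3482 ± 313 to 6712 ± 280, and P4HA1, a collagen prolyl hydroxylase, from 1625 ± 136 to 3656 ± 528. EGLN1, the oxygen-sensing prolyl hydroxylase, rose by 0.66 on the log2 scale. The list's median log2 fold change was 0.42. In the library labelled WT replicate 3 the members lay a median of 0.07 above the other WT libraries, and without it 13 of 19 members rose, with a median log2 fold change of 0.46 and an adjusted p = 0.224 with an estimated correlation.

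Genes of the unfolded protein and integrated stress response were higher by camera with the preset correlation (adjusted p = 1.05e-08), but not with an estimated correlation (adjusted p = 0.603 with an estimated correlation) or by fry (0.102). Of 24 measured members, 6 rose over all genes tested and 11 when adjusted over the list alone. HERPUD1, a component of endoplasmic reticulum protein degradation, rose from 2467 ± 540 to 5385 ± 190 (log2 fold change 1.15, SE 0.16, limma adjusted p = 0.0286). CREB3L2, a membrane-bound transcription factor, rose from 1583 ± 84.4 to 2987 ± 42.1, and MTHFD2, a mitochondrial folate enzyme, from 5172 ± 323 to 7618 ± 431. Reads of MTHFD2 are uncertain because 33.2% of its exonic bases overlap other genes. HSPA5, the main endoplasmic reticulum chaperone, was at 14299.8 ± 6116 in WT and 12984 ± 1798 in 4A and did not pass (limma adjusted p = 0.896). The members lay a median of −0.56 on the log2 scale from the other WT libraries in the library labelled WT replicate 3. Without it the list's median log2 fold change went from 0.50 to 0.37 and 14 members rose, with an adjusted p = 0.224 with an estimated correlation.

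Glycolysis genes rose in 4 of 20 cases over all genes tested and in 6 when adjusted over the list alone. PFKL, the liver-type phosphofructokinase, rose from 3579 ± 284 to 5781 ± 228 (log2 fold change 0.69, SE 0.089, limma adjusted p = 0.0239), and PFKFB3, PGK1 and ENO2 rose by 0.57, 0.53 and 0.54 on the log2 scale. camera's adjusted p was 0.00253, with an adjusted p = 0.603 with an estimated correlation. It was 0.0515 without WT replicate 1, 0.0739 without WT replicate 2 and 6.86e-08 without the library labelled WT replicate 3, where an estimated correlation gave 0.224. Over the 5 libraries that remain without WT replicate 3, 12 members rose. In the library labelled WT replicate 3 the members lay a median of 0.21 above the other WT libraries.

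**Figure D2:**
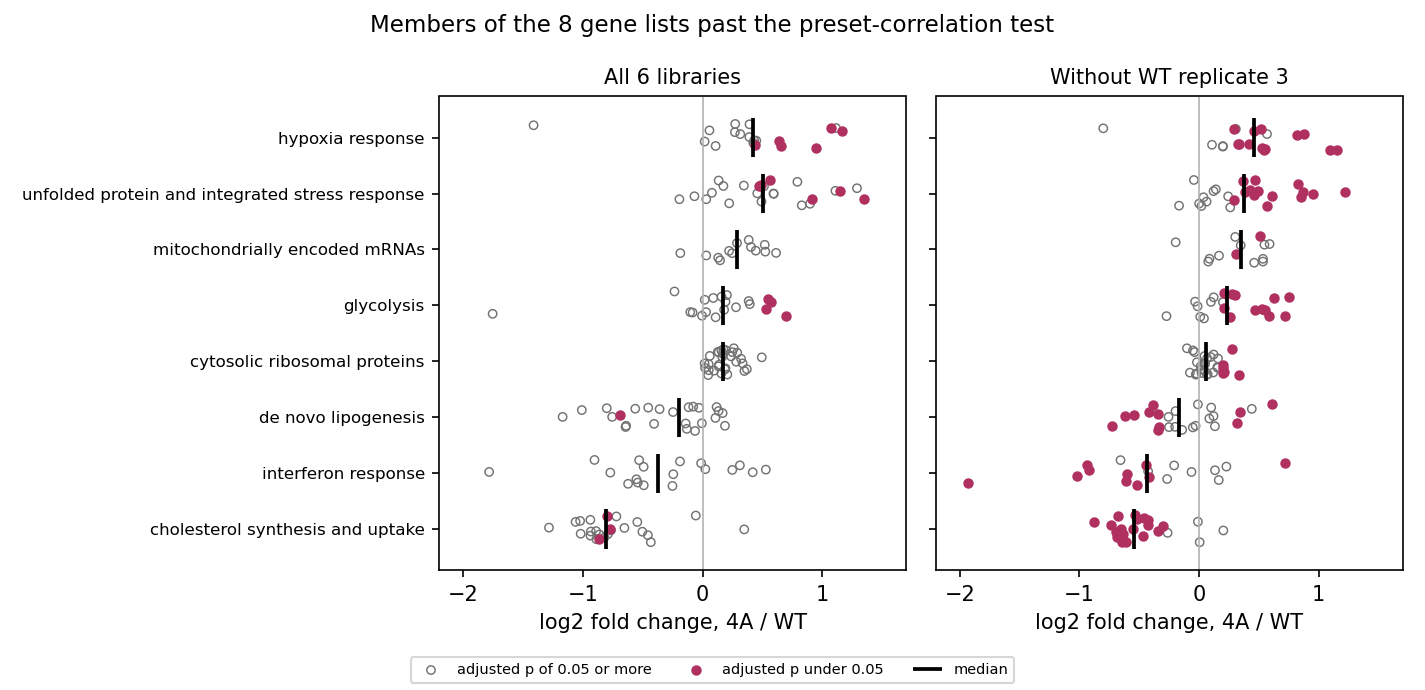
Log2 fold change of 4A over WT for each measured member of the 8 gene lists past the preset-correlation test, over all 6 libraries (left) and without the library labelled WT replicate 3 (right). Filled points are members with an adjusted p under 0.05 over all genes, open points the others, and black lines the list medians, which for cholesterol synthesis and uptake are −0.81 and −0.54.

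Cytosolic ribosomal protein genes had small positive log2 fold changes in all 30 members, with a median of 0.17, and 0 of 30 passed the limma threshold, also when adjusted over the list alone. RPL11 was at 24513 ± 4455 in WT and 34166.5 ± 2355 in 4A (log2 fold change 0.49, limma adjusted p = 0.102). camera's adjusted p was 1.17e-04, with an adjusted p = 0.603 with an estimated correlation. The members were a median of −0.34 from the other WT libraries in the library labelled WT replicate 3, and without it the median log2 fold change was 0.06, 6 members rose, and camera's adjusted p was 0.0361 with its variance trend, 0.147 without it and 0.714 with an estimated correlation. For the 13 mitochondrially encoded mRNAs, 0 passed, also when adjusted over the list alone, the median log2 fold change was 0.29, and camera's adjusted p was 0.00446, with an adjusted p = 0.603 with an estimated correlation and 0.111 without WT replicate 2. Of the 13, 2 rose without the library labelled WT replicate 3. MT-ND6 was at 4001 ± 689 in WT and 6117 ± 973 in 4A (limma adjusted p = 0.0845).

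Interferon-response genes were lower by camera (adjusted p = 0.0229), with an adjusted p = 0.603 with an estimated correlation, and 0 of 18 measured members passed over all genes tested. When adjusted over the list alone, 4 fell. STAT1, a signal transducer of interferon receptors, was at 2119.9 ± 292 in WT and 1459 ± 74.5 in 4A (log2 fold change −0.53, limma adjusted p = 0.0628), and HERC5, a ligase for the modifier ISG15, at 1251 ± 169 and 883 ± 42.6. The list's call was lost without WT replicate 1 (0.0761) and without WT replicate 2 (0.194). Without the library labelled WT replicate 3, where the members lay a median of −0.34 from the other WT libraries, 9 members fell and 1, ISG20, rose.

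The other 16 lists did not pass. Hexosamine and O-GlcNAc cycling genes had a camera adjusted p of 0.699, a median log2 fold change of −0.14, a mean of −0.021 and a test direction that was higher. Of its 9 members, GFPT1, the rate-limiting enzyme of the hexosamine pathway, rose from 2851 ± 22.2 to 4713 ± 16.7 (log2 fold change 0.72, SE 0.072, limma adjusted p = 0.0192). OGT and OGA, which add and remove O-GlcNAc, were at log2 fold changes of −0.22 and −0.14 and did not pass (limma adjusted p = 0.452 and 0.498). SR proteins and their kinases, known substrates and relatives of SRPK2, had 0 of 24 members past the threshold, also when adjusted over the list alone, and a camera adjusted p of 0.492. CLK2, a kinase of SR proteins, was closest at −0.59 (limma adjusted p = 0.0629). The spliceosome core had 0 of 32 past the threshold, 2 higher and 2 lower when adjusted over the list alone, and a camera adjusted p of 0.453. U2AF2, which binds the polypyrimidine tract, was at −0.34 (limma adjusted p = 0.0623). Among SR proteins and their kinases, 2 members rose and 6 fell without the library labelled WT replicate 3, CLK2 among the latter (limma adjusted p = 0.000482). In the spliceosome core 3 rose and 7 fell, U2AF2 among the latter (limma adjusted p = 0.000272), and in the hexosamine list 3 rose and 1 fell. camera did not call these lists there either, with adjusted p of 0.319 for SR proteins, 0.182 for the spliceosome core and 0.319 for the hexosamine list.

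Triglyceride and phospholipid synthesis (camera adjusted p = 0.260) had 1 of 24 past the threshold, PCYT2, which fell by 0.88 on the log2 scale and shares 28.1% of its exonic bases with other genes. Fatty acid oxidation (0.513) had ACADVL, which rose by 0.55, p53 targets (0.671) had BAX, which fell by 0.64, and transcripts cleared by nonsense-mediated decay (0.260) had SMG5, which fell by 0.50. Members past the threshold over all 6 libraries numbered 0 for the remaining lists. Their camera adjusted p values were 0.495 for cell cycle, 0.435 for oestrogen response, 0.916 for nuclear-encoded oxidative phosphorylation, 0.435 for luminal markers, 0.260 for basal markers, 0.435 for mesenchymal markers, 0.852 for haematopoietic markers, 0.435 for replication-dependent histones and 0.276 for immediate early genes. Without the library labelled WT replicate 3 the immediate early genes passed, as higher in 4A (0.0163), with an adjusted p = 0.516 with an estimated correlation. Without that library members past the threshold over all genes were 6 higher and 8 lower for oxidative phosphorylation, 2 and 4 for cell cycle, 4 and 0 for oestrogen response, 4 and 0 for luminal markers, 3 and 1 for mesenchymal markers and 5 and 1 for immediate early genes. They were 1 and 0 for basal markers, 1 and 0 for haematopoietic markers, 0 and 1 for histones, 3 and 4 for triglyceride and phospholipid synthesis, 3 and 6 for fatty acid oxidation, 5 and 2 for nonsense-mediated decay and 4 and 1 for p53 targets. Over all 6 libraries, adjusted over the list alone, members past 0.05 were 1 higher and 5 lower for triglyceride and phospholipid synthesis, 1 higher and 2 lower for fatty acid oxidation, 2 higher and 2 lower for nonsense-mediated decay, 1 lower for p53 targets and 2 higher for hexosamine genes. They were 2 higher and 1 lower for oxidative phosphorylation, and 2 higher each for luminal markers, mesenchymal markers and immediate early genes. Mean and median log2 fold changes differed in sign for fatty acid oxidation (−0.048 and 0.0096, test direction lower) and SR proteins (−0.066 and 0.0049, lower). They also differed for oxidative phosphorylation (0.024 and −0.013, lower) and luminal markers (−0.16 and 0.18, higher). Among the other splits of the 6 libraries into 3 and 3, the same list test called 3 to 9 lists.

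Markers of cell type were measured in every library. TFF1 and TFF3, secreted trefoil peptides that are oestrogen-induced in luminal breast cells, had 0 reads in all 6 libraries, which allows up to 0.117 to 0.129 counts per M reads (CPM). In normalised counts, ESR1, the oestrogen receptor, was at 4.69 to 10.3 (0.194 to 0.420 CPM). PGR, the progesterone receptor, was at 0 to 1.87 (0 to 0.0777 CPM). The values that follow are normalised counts too. Other luminal markers were expressed in every library: XBP1 was at 4222 to 13491, KRT8 at 6144 to 10340.0, KRT18 at 1323 to 1656, GATA3 at 208 to 292 and FOXA1 at 126 to 270.3. MUC1 was at 0 to 15.8 and SPDEF at 0 to 4.05. Of the 15 luminal markers listed, 9 passed the expression filter. VIM, vimentin, was at 3321 to 4410.0, with 24.4% of VIM's exonic bases shared with other genes. KRT19 was at 0 to 5.17 and ELF3 at 1.03 to 7.16 in 5 libraries, and they were at 2152 and 111 in the library labelled WT replicate 3. In that library EPCAM was at 1058, CLDN4 at 748 and CDH1 at 97.9, against highest values of 97.2, 23.4 and 18.4 in the others. XBP1, KRT8 and FOXA1 had their lowest values in it. Several basal markers were also higher in it, with ANXA1 at 993 and CAV1 at 575, against highest values of 273 and 172 in the others. On the log2 scale its median difference from the other WT libraries was 1.76 for measured basal markers and 0.021 for measured luminal markers. CDKN2A was at 6636 to 8854 and the neighbouring MTAP at 1437 to 2416. PTPRC, a marker of blood cells, was at 0 to 1.01.

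**Figure D3:**
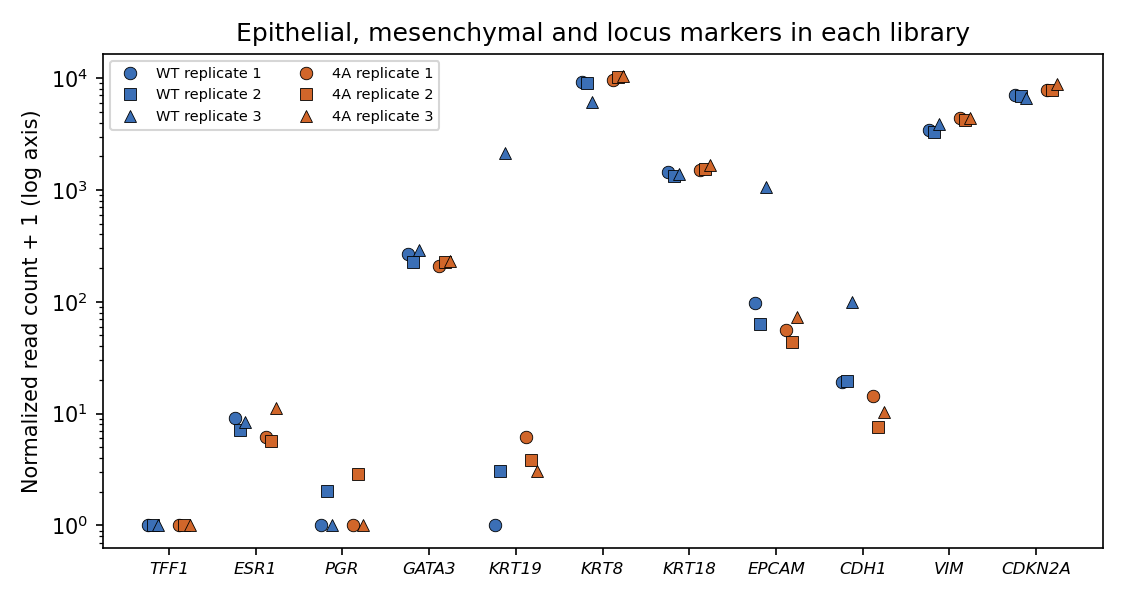
Normalised read counts plus 1 (log axis) of epithelial, mesenchymal and locus markers in each library, WT in blue and 4A in orange, with the mark shape giving the replicate number. TFF1 is at 0 in all 6 libraries, and KRT19 is at 2152 in the library labelled WT replicate 3 and at 0 to 5.17 in the others.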

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

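The tests with edgeR on recovered reads, TMM factors, pseudocounts, library weights, non-robust moderation and camera without the variance trend were chosen after the result was seen, as were an estimated correlation and fry without WT replicate 3 and removal of GC and length trends for other results than the count of genes. Depth limits values near the floor only; the 3 libraries per group limit the rest, and 1 of them, WT replicate 3, sets most of the spread. The 360 calls were 341 with library size scaling, 367 with TMM (358 shared), 402 with the stricter filter, 296 with limma-voom, 358 and 379 with pseudocounts of 0.5 and 4, 384 with non-robust moderation and 361 with edgeR, and scaling moved the median gene by under 0.03. Of 2357 alternative values of 118 named genes, 1865 kept direction and side of the threshold, 246 lost it, 240 gained it and 6 reversed. Many of the 118 did not pass over all 6 libraries, so for these keeping the side meant staying uncalled. Every named gene that had passed lost its call with the replicate block and on leaving out any library but WT replicate 3, where 0 genes were called. Unless stated, the cause was not tested.

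Counts of genes, and of those changed by at least 1 on the log2 scale, were 593 and 148 with no filter, 1519 and 302 with DESeq2, 4576 and 421 with library weights (weight 0.0954 for WT replicate 3), and 3889 and 290 with edgeR without WT replicate 3. Removal of GC and length trends gave 560. The replicate block gave 0 and 0 (2844 genes at an unadjusted limma p under 0.05), and 0 with that removal. Same-numbered libraries did not deviate together from their group means (correlations −0.040, −0.042 and −0.087). WT replicate 3 sets most of the deviations in its group, so this check cannot tell whether the numbers pair the samples. Leaving out each library, counts ranged from 0 to 3865 and 0 to 262, called lists from 5 to 9 and the SRPK2 log2 fold change from 0.17 to 2.09.

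With an estimated correlation 0 lists passed: adjusted p was 0.603 for cholesterol, lipogenesis, glycolysis, interferon, stress response, ribosomal and mitochondrial genes and 0.158 for hypoxia. Without WT replicate 3 again 0 passed: 0.224 for cholesterol, glycolysis, interferon, stress response and hypoxia, 0.549 for lipogenesis and mitochondrial genes, 0.714 for ribosomal genes. Fry called 1 list, hypoxia, with 0.201 for cholesterol, 0.428 for lipogenesis, 0.294 for glycolysis and interferon, 0.102 for stress response, 0.378 for ribosomal and 0.337 for mitochondrial genes. Fry without WT replicate 3 gave 0.179 for lipogenesis, 0.453 for ribosomal and 0.353 for mitochondrial genes, and passed cholesterol (0.0125), glycolysis, stress response and hypoxia (0.00916 each), interferon (0.0208), luminal markers (0.0233), immediate early genes (0.0397) and the spliceosome core (0.0424). Lipogenesis had 0.0530 with library weights. Camera without the variance trend and without WT replicate 3 gave 0.192 for lipogenesis and 0.147 for ribosomal genes, and edgeR's fit without that library 0.105 for ribosomal genes. Mitochondrial genes had 0.113 after removal of GC and length trends. Leaving out each library, adjusted p ranged from 6.86e-08 to 0.0739 for glycolysis, 0.00109 to 0.194 for interferon and 3.3e-06 to 0.111 for mitochondrial genes.

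Reversed directions were far from the threshold. Oxidative phosphorylation turned higher with edgeR (0.862), fry (0.9501) and no filter (0.781). By camera it also did without WT replicate 1 (0.730), WT replicate 2 (0.896), 4A replicate 1 (0.705) or 4A replicate 2 (0.798). Its range over all libraries left out, reversed or not, was 0.422 to 0.896. Histones turned lower without WT replicate 3 (range over libraries left out 0.179992 to 0.572), in those 5 libraries also by edgeR (0.612), fry (0.567), an estimated correlation (0.714) and camera without the trend (0.575), and over all 6 with library weights (0.607). Basal markers turned higher by camera without WT replicate 3 (0.839), in those 5 libraries also by edgeR (0.780) and an estimated correlation (0.864). They did so over all 6 with weights (0.850). Their range over all libraries left out, reversed or not, was 0.0746 to 0.839. By camera, haematopoietic markers turned higher without WT replicate 1 (0.885) or 4A replicate 3 (0.941), and the hexosamine list lower without WT replicate 1 (0.756). Ranges over all libraries left out, reversed or not, were 0.637 to 0.941 and 0.319 to 0.890. ACSS2 turned to 0.085 with edgeR without WT replicate 3 and 0.057 with weights (range −0.26 to 0.085), CD19 to 0.016 with weights, and CD74 ranged from −0.51 to 0.028.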

Other observations

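Most tests and single-library values in this part were chosen after the result was seen. Leaving out each library in turn had been fixed beforehand. So had the list tests over all 6 libraries with the preset and an estimated correlation, apart from camera's variance trend. The genes named here for the library labelled WT replicate 3 were picked from its most extreme differences, and no gene group was tested. The pick was limited to protein-coding genes past the expression filter with a high value in at least 1 library. KRT19, at 2152 in that library, did not pass the filter and could not be picked. DKK1, a secreted Wnt inhibitor, was at 2814 there and at 23.8 to 34.7 in the other 5 libraries, KITLG, the ligand of KIT, at 6384 against 322 to 421, and BMP4 at 2971 against 122 to 193. SPRY4 and DUSP6, which are feedback inhibitors of MAP kinase signalling, were at 679 and 557 against highest values of 30.0 and 27.9 elsewhere. CD44, a hyaluronan receptor, was at 645 against a highest value of 23.6. PPP1R15A, a phosphatase subunit of the stress response, was at 1805 against 8872 to 10653, and GADD45A, a stress-induced growth arrest gene, at 1382 against 4243 to 6688. Zinc finger genes of chromosome 19 were also examined, without a test. Of 194, 49 were at least 2-fold lower in that library than in WT replicates 1 and 2, and 9 at least 2-fold higher. Of the 28 between 57 and 58 Mb, 15 were lower and 2 higher by that much, and 0 were lower by that much in 4A.

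The first pattern weighed is that the library labelled WT replicate 3 lay apart from the other 5. It had 25566538 reads, within the range of the others. Against the mean of WT replicates 1 and 2, 1510 genes were at least 2-fold lower and 1145 at least 2-fold higher, which argues against depth or scaling. Between WT replicates 1 and 2, 630 genes were at least 2-fold apart. The filter drops genes expressed only in WT replicate 3, so the count of higher genes is a lower bound. Of the 4A libraries, 0 was closer to WT replicates 1 and 2 than to its own group, which argues against a swap between the groups. Other cells that gave a minority of the RNA could not, scaling aside, lower a gene by more than 1 on the log2 scale. Yet 523 of 11302 genes at 100 or more were lower by that much, against 0 between WT replicates 1 and 2. The bound is on the share of RNA, so a minority of cells with more RNA each is not excluded. SRPK2, 14.3-fold lower there, may have changed other genes, but with 1 such library this cannot be told apart from another difference of that library. A culture or cell stock that differed, or a sample from outside the group, stays open and untested.

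The second pattern is that TFF1, TFF3, PGR and ESR1 were near 0 in all 6 libraries labelled MCF7. The luminal markers MUC1 (0 to 15.8) and SPDEF (0 to 4.05) were too. KRT19 (0 to 5.17), ELF3 (1.03 to 7.16), CLDN4 (5.06 to 23.4) and CDH1 (6.56 to 18.4) were low in the libraries other than WT replicate 3. In WT replicate 3, KRT19 was at 2152 and CLDN4 at 748, but ELF3 was only at 111 and CDH1 at 97.9. XBP1 (4222 to 13491), GATA3 (208 to 292), KRT8, KRT18 and FOXA1 were expressed in every library. Too few reads do not account for the pattern, since 14759 genes had 10 or more reads in every library. MCF-7 is known, as background, to carry a deletion of CDKN2A, and the lowest CDKN2A count was 6833 reads, which argues against MCF-7 cells that kept that deletion and lost TFF1, TFF3, PGR and ESR1 transcripts. A hypothesis is that the cells may differ from MCF-7 as it is commonly described; the files hold no genotype that could test it.

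The third pattern is lower cholesterol synthesis genes with higher hypoxia and stress-response genes in 4A, as called with the preset correlation. None of the 3 calls held in camera with an estimated correlation (adjusted p 0.603, 0.158 and 0.603, and 0.224 for each without WT replicate 3). The estimated correlations over all 6 libraries were 0.76, 0.032 and 0.37. That setting also cuts the degrees of freedom to those of the few libraries, so it cannot tell whether correlation between genes made the calls. The library labelled WT replicate 3 is not the whole cause, since without it the medians on the log2 scale were −0.54, 0.46 and 0.37. GC content and transcript length are not either: after removal of their trends those medians were −0.54 (−0.536 before rounding), 0.45 and 0.39, and the 20, 13 and 14 members past the threshold all stayed past it. The mutant itself and a difference in density, nutrients or oxygen between the cultures may each account for it, and neither was tested.

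Of the 10 splits of the 6 libraries into 3 and 3, the real one was the 1 of 10 with 360 genes, against a highest of 0 in the others, and the 1 of 10 with 91 genes changed by at least 1 on the log2 scale, against 0. For the gene lists, 5 of 10 splits, the real one included, called 8 or more, with a highest of 9 in the others. The splits are too few for a share under 0.05.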
